A study of Danio rerio with 24 samples.

How the data were processed

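RNA of adult zebrafish testis was measured on 24 1-colour Agilent arrays, 6 for each of 4 embryonic doses of atrazine. Per the file headers, the spot intensities came from Feature Extraction 11.5.1.1 (11.5 per the submitters' processing notes), which subtracted background and corrected spatial trends but did not normalize between arrays. The authors' deposited value table holds a log2 intensity per probe, and the software that made it is not given in the sources used here. Its columns correlated with the log2 scanner signal at 0.984 to 1.00 across probes, which shows a log2 scale less about each array's 75th percentile, with no centring of probes and the direction of signal, and the exact offset stays unknown. Its medians for replicates 1 to 6 were -2.54, -2.75, -3.02, -2.85, -2.60 and -2.96 at 0 ppb, -2.88, -2.93, -2.86, -2.46, -2.57 and -2.40 at 0.3 ppb, -2.94, -2.85, -2.92, -2.76, -2.63 and -2.76 at 3 ppb and -3.23, -2.79, -2.89, -2.84, -2.59 and -2.92 at 30 ppb. The authors' deposited probe lists give a log2 value and a p-value per probe, and how they were tested, adjusted or signed is not given in the sources used here. A deposited list of genes altered at every dose was read as empty and not used here.

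Control spots and the spots marked as non-uniform or population outliers were left out, and saturated spots were kept. The log2 of the processed signal minus each array's 75th percentile was averaged over the spots of a probe. Symbols came from a RefSeq gene table (assembly GRCz12tu, used for names only), which matched 13710 of 15090 RefSeq target names. Of 128291 probes 39952 have 1 symbol and 88339 have none here, and 89208 target names gave 13547 named genes. Each gene or unnamed target was represented by its probe with the highest mean over all arrays, kept where well above background on at least 6 arrays, which left 70490, of them 13302 named. Missing values were 1.52% of the total, and a comparison needed at least 3 measured arrays per group. The median residual SD was 0.913 (log2), which with 6 arrays per group sets the precision.

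Two-sided moderated tests of limma 3.58.1 in R 4.3.3 were fitted to all 24 arrays, by an own least-squares fit that keeps missing values, with limma's squeezeVar. They gave each dose against 0 ppb, the mean of the doses, a trend over dose rank, differences between doses and an F test, with Benjamini-Hochberg adjustment per comparison and a call at an adjusted p under 0.05. The 35 gene lists were tested with limma's camera (preset correlation 0.01, adjusted over 35 lists and 3 doses) and fry, after missing values were filled with the group mean, and a list level is the mean deviation of its members from their medians over the arrays. The groups, tests, gene lists and the rule for named genes were set before the data were examined. The rule took, per dose, the 4 smallest p in each direction because no gene was called, 4 members with the smallest p in the direction of each called list (the first 2 of those reported are printed), any called member, a panel of 16 reproductive genes, and 5 symbols with the largest change from each deposited list. Named outside the rule, after their values were seen, were members that passed over their list alone, genes with the smallest p in the mean, trend, F and between-dose tests, and the most abundant genes of other tissues. Some genes that these choices name are not reported here.

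The tests were checked on simulated data with noise that was independent between genes, 50 genes for each log2 change of 1, 2, 3 and 4 among 70490. The percent called was 4, 38, 80 and 86 at 0.3 ppb (4 false of 108 calls), 0, 34, 72 and 88 at 3 ppb (6 of 103) and 2, 34, 64 and 94 at 30 ppb (0 of 97). A meiosis list of 14 genes shifted by 1 (median residual SD 1.72) moved up at each dose and was called at 0.3 ppb (adjusted p = 1.21e-06 by camera), not called at 3 ppb (0.582) and called at 30 ppb (6.50e-06), with 0 lists called at the other doses.

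Alternatives set before the data were examined were normexp (offset 50, on the median spot and background signals, as the mean signal was not analysed here), quantile and median scaling, the authors' deposited value table, no background filter or a filter on all 24 arrays, the mean of a gene's probes, every probe, only the 12 arrays compared, replicate (slide) or scan-day blocks, array weights, a trended robust variance, a plain two-sample test, an unadjusted p under 0.05 with a 1.5-fold change, an estimated correlation, fry, the controls split 3 and 3, and each array left out. Added after seeing the data were marked spots kept, named genes alone, and fits without the 4 libraries low in germ cell transcripts, without 0 ppb replicate 6 and 30 ppb replicates 1 and 6, without both sets (also with the replicate block), without slides 1 and 6, and without the 4 libraries with an estimated correlation. Scaling moved the median of all genes by over 0.1 (log2) for quantile scaling (0.15 at 0.3 and 0.22 at 3 ppb), median scaling (-0.11 at 0.3 and 0.17 at 30 ppb) and normexp (-0.19 at 30 ppb).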

Results

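Testis RNA was taken from adult zebrafish of the AB strain, 5 to 6 months after fertilization, that had been exposed to the herbicide atrazine only as embryos, from 1 to 72 hours after fertilization. The groups were 0, 0.3, 3 and 30 ppb with 6 replicates each, 24 arrays in all. Each sample was labelled with Cy3 and hybridised to an array of 180880 features. The labels do not say whether the replicates are separate fish, so p-values measure only the spread between these samples. Each of 6 slides held 1 array of each dose and 1 replicate number. Dose always sat at the same array position, so dose and position cannot be told apart.

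Spots well above background made up 35.8% of the array in 0 ppb replicate 6, 43.0% in 30 ppb replicate 1, 59.4% in 3 ppb replicate 6 and 65.1% to 88.7% in the others. The scanner marked 15.2% of spots as outliers in 30 ppb replicate 1, 13.5% in 30 ppb replicate 6 and 4.65% in 0 ppb replicate 6. In 30 ppb replicate 1, 41.1% of tested values sat at its lowest value of -4.31, among them those of fabp4a, igfbp5b and desmb. Correlations between arrays ran from 0.576 to 0.967 across genes, which are not independent replicates. The number of arrays limits the precision of every value below.

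Germ cell transcripts were low in 4 of the 24 libraries. Meiosis genes, as the mean deviation of the list from each gene's median over all arrays, stood at a log2 level of -5.14 in 0 ppb replicate 1, -4.25 in 0 ppb replicate 6, -3.52 in 0.3 ppb replicate 4 and -2.16 in 3 ppb replicate 6. Pancreas markers stood at 9.11 in 0 ppb replicate 1. Fibroblast and matrix genes stood at 5.01 in 0 ppb replicate 6 and 4.15 in 0.3 ppb replicate 4, and smooth muscle markers at 5.66 in 3 ppb replicate 6. The first principal component, with 36.9% of the variance, separated these libraries. Because 2 of the 4 are controls and none is a 30 ppb library, each gene group below is also given without these libraries (without the 4), in values chosen after seeing the data.

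**Figure D1:**
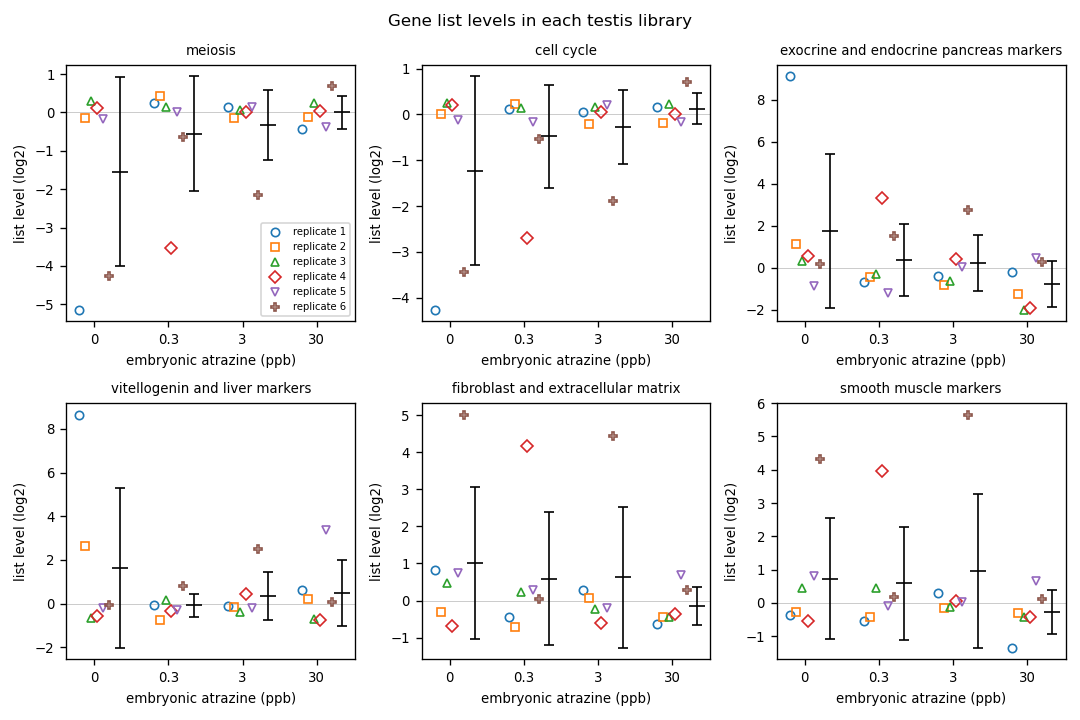
Level of 6 gene lists in each library (log2, mean deviation of the members from their median over the 24 arrays) by embryonic atrazine dose (ppb), with a marker per replicate and the mean ± SD per group. Meiosis genes lie at -5.14 in 0 ppb replicate 1, where pancreas markers lie at 9.11.

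At 0.3 ppb, the lowest embryonic dose, meiosis, cell cycle and spermatid lists rose, by median log2 changes of 1.1, 0.79 and 0.88. Markers of liver and pancreas fell, to medians of -1.88 and -1.45, as did the thyroid hormone axis, at -0.84. Without the 4, these 6 medians were -0.05, -0.08, 0.05, -0.32, -0.19 and -0.21, and none was called with an estimated correlation (adjusted p = 0.670 to 0.809). No single gene passed the test over all genes. For dio2, the deiodinase that activates thyroid hormone, the log2 level was -3.14 ± 1.11 (SD, 6 libraries) against 0.83 ± 3.46 at 0 ppb, a change of -3.96 ± 1.13 (SE, adjusted p = 0.993), lower on 4 of 6 slides.

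In the account of gene groups, medians and values of single genes are log2 changes from 0 ppb, the latter ± SE over 6 libraries per group unless other numbers are given, with the change without the 4 in brackets, and none of these genes passed the test. With 1 library left out, 380 of 2712 changes of named genes moved by over 1.5 times or turned in sign, and outside the reproductive panel those of changes given below are printed where that library stood far from its group or is not 1 of the 4. Lists were tested by camera, with reversed for its direction and estimated-correlation p for its adjusted p with an estimated correlation. Bracketed values without the 4, values by block (slide) and ranges (in all, over 34 alternatives) are adjusted p, slides are counted by the list level of the dose against that of 0 ppb on the same slide, and single libraries are given whose omission ends or reverses a call, with the adjusted p, or moves the median by over 1.5 times, with that median. Meiosis genes rose, 14 of 14 above 0, by a median of 1.1 (adjusted p = 0.000120, estimated-correlation p = 0.763). Here sycp1, a protein of the synaptonemal complex, was at 1.33 ± 0.78 (0.61) and psmc3ip, a cofactor of meiotic recombination, at 1.44 ± 0.99 (0.04). Meiosis was at -0.05 without the 4 (0.597, reversed), with 0.000253 by block, 1.62e-08 to 0.960 in all and 4 of 6 slides higher. It lost the call without 0 ppb replicate 1 (0.272, median 0.23) or 6 (0.246, median 0.56), and the median moved without 0.3 ppb replicate 4 (1.76). The 31 cell cycle genes rose by a median of 0.79, 29 above 0 (adjusted p = 2.21e-06, estimated-correlation p = 0.763). Of these, mki67, a marker of dividing cells, was at 1.17 ± 0.76 (0.09) and cdk1, the kinase that drives entry into mitosis, at 1.1 ± 0.79 (0.15). The cell cycle was at -0.08 without the 4 (0.00409, reversed), with 8.43e-06 by block, 3.77e-11 to 0.763 in all and 3 of 6 slides higher. The call was lost without 0 ppb replicate 1 (0.498, median 0.13) or 6 (0.177, median 0.32), and the median moved without 0.3 ppb replicate 4 (1.28). Spermatid and sperm flagellum genes rose, 23 of 24 above 0, by a median of 0.88 (adjusted p = 2.11e-06, estimated-correlation p = 0.763). Here zmynd10, an assembly factor of ciliary dynein arms, was at 1.67 ± 1.00 (0.23, n = 6 and 5) and odf2b, an outer dense fibre protein, at 1.06 ± 0.71 (0.19). Spermatid genes were at 0.05 without the 4 (0.798), with 1.22e-05 by block, 2.05e-14 to 0.962 in all and 4 of 6 slides higher. The call ended without 0 ppb replicate 1 (0.324, median 0.20) or 6 (0.128, median 0.45), and the median moved without 0.3 ppb replicate 4 (1.52). The 18 spermatogonial and early germ cell markers rose by a median of 0.61, 14 above 0 (adjusted p = 0.00229, estimated-correlation p = 0.763). Of these, id4, a regulator of germline stem cells, was at 1.17 ± 0.43 (0.39) and dazl, a germ-cell RNA-binding protein, at 1.73 ± 1.07 (-0.11, n = 6 and 5). Spermatogonial markers were at -0.04 without the 4 (0.583, reversed), with 0.00402 by block, 7.43e-06 to 0.902 in all and 3 of 6 slides higher. Their call was lost without 0 ppb replicate 1 (0.167, median 0.21) or 6 (0.367), and the median moved without 0.3 ppb replicate 1 (0.41) or 4 (1.06). Oocyte markers rose, 20 of 22 above 0, by a median of 0.49 (adjusted p = 0.00832, estimated-correlation p = 0.809). Here btg4, a factor of maternal mRNA decay, was at 0.69 ± 0.67 (0.46) and zp2.1, an egg-coat protein, at 0.99 ± 0.99 (2.1). Oocyte markers were at 0.46 without the 4 (0.292), with 0.0109 by block, 8.88e-06 to 0.897 in all and 4 of 6 slides higher. They lost the call without 0 ppb replicate 6 (0.531, median 0.16), or 0.3 ppb replicate 1 (0.0571), 3 (0.0879) or 5 (0.0626, median 0.32), and the median moved without 0 ppb replicate 1 (0.27), or 0.3 ppb replicate 4 (0.91) or 6 (0.31). Omission of 1 library gave zp2.1 at 0.64 without 0 ppb replicate 3, zp2.1 at 1.60 without 0.3 ppb replicate 2, btg4 at 1.24 without 0.3 ppb replicate 4, and zp2.1 at 0.59 without 0.3 ppb replicate 6.

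Liver and vitellogenin markers fell, 19 of 20 below 0, to a median of -1.88 (adjusted p = 1.63e-05, estimated-correlation p = 0.763). Here fgg, a fibrinogen chain made in liver, was at -3.36 ± 1.65 (-1.39) and apoa2, an apolipoprotein, at -3.16 ± 1.79 (-1.69). Liver markers were at -0.32 without the 4 (0.520), with 0.000141 by block, 2.58e-10 to 0.960 in all and 3 of 6 slides lower. The call was lost without 0 ppb replicate 1 (0.731, median -0.21). The 23 pancreas markers fell to a median of -1.45, 22 below 0 (adjusted p = 0.000794, estimated-correlation p = 0.809). Of these, ctrb.2, a chymotrypsinogen, was at -2.41 ± 1.51 (-1.24) and prss59.1, a trypsinogen, at -2.29 ± 1.56 (-1.95). Pancreas was at -0.19 without the 4 (0.0126), with 0.00300 by block, 1.80e-07 to 0.809 in all and 4 of 6 slides lower. The call ended without 0 ppb replicate 1 (0.333, reversed, median 0.17). Adipocyte markers fell, 11 of 12 below 0, to a median of -0.64 (adjusted p = 0.00883, estimated-correlation p = 0.670). Here scd, a stearoyl-CoA desaturase, was at -1.30 ± 0.63 (-0.26) and lpla, a lipoprotein lipase, at -1.58 ± 0.77 (-0.53). Adipocyte markers were at -0.16 without the 4 (0.520), with 0.0208 by block, 0.000532 to 0.874 in all and 4 of 6 slides lower. Their call was lost without 0 ppb replicate 1 (0.167). The 24 cholesterol synthesis genes fell to a median of -0.35, 18 below 0 (adjusted p = 0.0348, estimated-correlation p = 0.763). Of these, srebf2, a transcription factor of cholesterol synthesis, was at -0.95 ± 0.46 (-0.32) and dhcr7, a late enzyme of cholesterol synthesis, at -1.03 ± 0.55 (-0.47). Cholesterol synthesis was at -0.18 without the 4 (0.00520), with 0.0706 by block, 3.05e-05 to 0.763 in all and 4 of 6 slides lower. It lost the call without 0 ppb replicate 2 (0.0578), 3 (0.220), 4 (0.231) or 6 (0.189, median -0.16), or 0.3 ppb replicate 4 (0.341, median -0.18), 5 (0.0889) or 6 (0.156), or 30 ppb replicate 1 (0.0579), and the median moved without 0 ppb replicate 1 (-0.56). Single omissions gave lpla at -0.51 and ctrb.2 at -0.40 without 0 ppb replicate 1.

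Thyroid hormone axis genes fell, 10 of 11 below 0, to a median of -0.84 (adjusted p = 0.000139, estimated-correlation p = 0.670). Here dio2 was at -3.96 ± 1.13 (-2.19) and dio3a, a deiodinase that inactivates thyroid hormone, at -1.49 ± 0.51 (-0.70). The thyroid axis was at -0.21 without the 4 (0.0171), with 0.000554 by block, 3.35e-05 to 0.695 in all and 6 of 6 slides lower. It had another median without 0 ppb replicate 1 (-0.45) or 6 (-0.50), or 0.3 ppb replicate 4 (-0.53). The 21 IGF and insulin signalling genes fell to a median of -0.74, 18 below 0 (adjusted p = 0.000815, estimated-correlation p = 0.670). Of these, igfbp2a, an IGF-binding protein, was at -2.52 ± 0.93 (-0.62) and igf3, a gonadal IGF of fish, at -1.01 ± 0.45 (-0.92). The IGF list was at -0.11 without the 4 (0.0831), with 0.00137 by block, 7.27e-06 to 0.695 in all and 5 of 6 slides lower. The median moved without 0 ppb replicate 1 (-0.26) or 6 (-0.45). Neuroendocrine and monoamine genes fell, 35 of 41 below 0, to a median of -0.42 (adjusted p = 0.000794, estimated-correlation p = 0.670). Here htr5aa, a serotonin receptor, was at -1.74 ± 0.68 (-0.35) and ghra, a growth hormone receptor, at -1.1 ± 0.48 (-0.27). Neuroendocrine genes were at 0.02 without the 4 (0.508, where camera kept its direction), with 0.00114 by block, 0.000283 to 0.874 in all and 4 of 6 slides lower. The call was lost without 0.3 ppb replicate 4 (0.0767), and the median moved without 0 ppb replicate 1 (-0.23) or 6 (-0.19). The 32 xenobiotic metabolism genes fell to a median of -0.51, 25 below 0 (adjusted p = 0.00198, estimated-correlation p = 0.759). Of these, nqo1, a quinone reductase, was at -1.34 ± 0.57 (-0.48) and abcg2a, an efflux transporter, at -1.11 ± 0.53 (-0.33). Xenobiotic metabolism was at -0.09 without the 4 (0.112), with 0.00457 by block, 3.13e-05 to 0.759 in all and 4 of 6 slides lower. The call ended without 0 ppb replicate 1 (0.199, median -0.21). Adjusted over the list alone, dio2 (adjusted p = 0.0207) and dio3a (0.0420) passed, 2 genes against 0 adjusted over all genes, and both were lower at 0.3 ppb, on 4 and 6 of 6 slides. Of these 2, 0 passed without the 4, 0 without 0 ppb replicate 6, or 0.3 ppb replicate 2, and 1 without 0 ppb replicate 1 or 3, or 0.3 ppb replicate 4 or 6, or 3 ppb replicate 2 or 5, or 30 ppb replicate 4. Leaving 1 library out gave nqo1 at -0.64 and abcg2a at -0.44 without 0 ppb replicate 1.

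Among the genes with the smallest p in each direction at 0.3 ppb, with the change without the 4 last in each bracket, si:ch211-272h9.3 (1.33 ± 0.34, 0.77), si:dkey-83f18.3 (1.49 ± 0.41, 0.71), si:dkey-81n2.2 (1.30 ± 0.35, 0.81) and si:dkey-83f18.5 (1.21 ± 0.34, 0.68) lay above 0 ppb. Of the 2 probes of si:ch211-272h9.3, 1 had the sign given. Those below 0 ppb included stxbp5l, a tomosyn-family gene (-2.44 ± 0.65, -2.13), ugt5a1, a UDP-glucuronosyltransferase, and slc17a6b, a vesicular glutamate transporter (-1.46 ± 0.40, -0.69). Each of these had an adjusted p of 0.993 by limma. ugt5a1 was not well above background on any of the 6 arrays at 0.3 ppb and above it on 3 at 0 ppb, so its p rests on values below background. The means, -4.61 at 0 and -7.18 at 0.3 ppb, both hold such values, so no fold is given.

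A panel of reproductive genes was followed at every dose, and none of its 15 measured members was called at 0.3 ppb; no probe was matched to hsd3b1 here. Brackets hold the change without the 4 and its range with 1 library left out. In steroid synthesis, star, which delivers cholesterol to mitochondria, was at 0.54 ± 1.24 (-0.42, -0.27 to 1.45), cyp17a1 at 0.53 ± 1.22 (-0.87, -0.41 to 1.25), cyp11c1, an enzyme of 11-ketotestosterone synthesis, at 0.55 ± 0.84 (-0.09, 0.01 to 1.18) and cyp19a1a, the gonadal aromatase, at -0.45 ± 0.38 (-0.17, -0.60 to -0.23). Receptor values were ar -0.41 ± 0.32 (0.06, -0.54 to -0.15), esr1 -0.54 ± 0.32 (-0.27, -0.75 to -0.33), esr2a -0.62 ± 0.50 (-0.08, -0.89 to -0.19), esr2b -0.62 ± 0.54 (-0.29, -0.96 to -0.19), fshr 0.26 ± 0.84 (-0.48, -0.30 to 0.73) and lhcgr -0.46 ± 0.46 (-0.24, -0.61 to -0.28). Among signals of the gonadal soma, values were amh 1.06 ± 1.31 (-0.37, -0.08 to 1.92), insl3 0.46 ± 1.25 (-0.58, -0.79 to 1.36), igf3 -1.01 ± 0.45 (-0.92, -1.36 to -0.69), gsdf 0.72 ± 1.24 (-0.58, -0.32 to 1.59) and dmrt1 0.83 ± 0.94 (-0.34, 0.12 to 1.42). Probes of fshr, esr1, cyp17a1 and dmrt1 differed in sign. Far from its group was 1 library, with esr2b at -0.19, dmrt1 at 1.42, amh at 1.92, gsdf at 1.59 and cyp11c1 at 1.18 without 0.3 ppb replicate 4.

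Lists called at another dose but not at 0.3 ppb, with adjusted p and the median without the 4 libraries, were chromatin modifiers at 0.20 (0.0623, -0.11), endothelium at -0.34 (0.176, -0.04), skeletal muscle at 0.27 (0.193, -0.01) and fibroblast genes at -0.43 (0.302, -0.10). The others were granulosa markers at 0.26 (0.783, -0.37), immediate early genes at 0.00 (0.815, -0.29), macrophage markers at -0.20 (0.895, -0.18) and smooth muscle at -0.20 (0.962, -0.23). Called lower only without the 4 were immediate early genes (adjusted p = 2.77e-05), sex steroid signalling (0.000974), granulosa markers (0.00520), heat shock (0.00725), oxidative stress (0.00725), chromatin modifiers (0.0147), circadian clock (0.0171) and Sertoli cell markers (0.0171), with adjusted p = 0.649 to 0.655 with an estimated correlation. Of 70490 genes and unnamed targets tested at 0.3 ppb, limma called 0 (smallest adjusted p = 0.993), with 2173 at an unadjusted p under 0.05, 670 of them higher and 1503 lower. A plain two-sample test also called 0, with 981 at that p, as did limma with the slide as a block, with 3507, and with the scan day as a block, with 3670. The median of all genes was -0.05. Without the 4, 0 were called and 1770 lay under 0.05. The count of 2173 became 3625, 3581 and 4226 without 0 ppb replicates 2, 3 and 4 in turn, and 3998 without 0.3 ppb replicate 4. Camera called 13 of 35 lists at 0.3 ppb, and 0 with an estimated correlation or by fry.

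At 3 ppb, cell cycle genes rose by a median log2 change of 1.05, spermatid genes by 1.08 and meiosis genes by 1.36, each higher on 3 of 6 slides. Chromatin modifiers rose by 0.24, and pancreas, liver and thyroid lists fell to -1.62, -1.44 and -0.64. Without the 4, these 7 medians were -0.03, -0.05, 0.05, -0.02, -0.68, -0.48 and -0.17. With the preset correlation, camera then still called the pancreas list. Camera with an estimated correlation called none of them, over all libraries (adjusted p = 0.670 to 0.809) or without the 4 (0.649 to 0.962). The gene with the smallest p was zgc:158785, at -1.95 ± 0.60 (± SE, -0.74 without the 4, adjusted p = 0.911 by limma), and no single gene passed.

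Cell cycle genes rose, 30 of 31 above 0, by a median of 1.05 (adjusted p = 3.87e-13, estimated-correlation p = 0.670). Here plk1, a mitotic kinase, was at 1.15 ± 0.74 (0.02) and tyms, thymidylate synthase, at 1.48 ± 0.98 (-0.03). The cell cycle was at -0.03 without the 4 (0.702, reversed), with 2.77e-12 by block, 7.15e-18 to 0.962 in all and 3 of 6 slides higher. The median changed without 0 ppb replicate 1 (0.36) or 6 (0.56). The 24 spermatid and sperm flagellum genes rose by a median of 1.08, 24 above 0 (adjusted p = 9.57e-13, estimated-correlation p = 0.670). Of these, zmynd10 was at 1.95 ± 1.00 (0.00, n = 6 and 5) and rsph9, a radial spoke protein, at 1.57 ± 0.86 (-0.04, n = 6 and 5). Spermatid genes were at -0.05 without the 4 (0.668, reversed), with 1.87e-11 by block, 2.61e-16 to 0.962 in all and 3 of 6 slides higher. They took another median without 0 ppb replicate 1 (0.40) or 6 (0.65). Meiosis genes rose, 13 of 14 above 0, by a median of 1.36 (adjusted p = 2.48e-08, estimated-correlation p = 0.670). Here sycp1 was at 1.52 ± 0.78 (0.41) and psmc3ip at 1.68 ± 0.99 (0.08). Meiosis was at 0.05 without the 4 (0.507), with 9.96e-08 by block, 1.20e-10 to 0.929 in all and 3 of 6 slides higher. It had another median without 0 ppb replicate 1 (0.54) or 6 (0.81). The 22 oocyte markers rose by a median of 0.75, 22 above 0 (adjusted p = 2.02e-07, estimated-correlation p = 0.670). Of these, org, an oogenesis-related gene, was at 1.41 ± 0.96 (-0.02) and btg4 at 0.92 ± 0.67 (0.54). Oocyte markers were at 0.66 without the 4 (1.94e-05), with 2.74e-07 by block, 6.42e-11 to 0.695 in all and 4 of 6 slides higher. The median moved without 0 ppb replicate 6 (0.49), or 3 ppb replicate 3 (0.14). In 3 ppb replicate 3 their level was 2.71, against 0.35 in the next 3 ppb library, and without it the adjusted p was 0.0333. Spermatogonial and early germ cell markers rose, 16 of 18 above 0, by a median of 0.85 (adjusted p = 1.81e-06, estimated-correlation p = 0.670). Here dazl was at 2.01 ± 1.07 (-0.03, n = 6 and 5) and ddx4, the Vasa RNA helicase, at 1.98 ± 1.17 (0.07). Spermatogonial markers were at 0.03 without the 4 (0.0393), with 3.33e-06 by block, 7.09e-09 to 0.695 in all and 6 of 6 slides higher. The median changed without 0 ppb replicate 1 (0.53) or 6 (0.55). Omission of 1 library gave btg4 at 0.44 without 3 ppb replicate 3.

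The 27 DNA methylation and chromatin modifiers rose by a median of 0.24, 22 above 0 (adjusted p = 0.000132, estimated-correlation p = 0.670). Of these, dnmt3bb.3, a DNA methyltransferase, was at 1.32 ± 0.95 (0.16) and prmt1, an arginine methyltransferase, at 0.51 ± 0.39 (0.04). Chromatin modifiers were at -0.02 without the 4 (0.890, where camera kept its direction), with 0.000184 by block, 2.97e-07 to 0.985 in all and 3 of 6 slides higher. They took another median without 0 ppb replicate 1 (0.10). Immediate early genes rose, 15 of 26 above 0, by a median of 0.16 (adjusted p = 0.0262, estimated-correlation p = 0.809). Here nr4a1, an orphan nuclear receptor, was at 1.18 ± 0.51 (0.18) and fosab, a subunit of AP-1, at 0.56 ± 0.37 (0.09). Immediate early genes were at -0.22 without the 4 (0.0147, reversed), with 0.0262 by block, 7.74e-05 to 0.889 in all and 4 of 6 slides higher. Their call was lost without 0 ppb replicate 1 (0.842, median -0.17, where camera kept its direction), 2 (0.134, median 0.03) or 4 (0.101, median 0.09), or 3 ppb replicate 6 (0.793, reversed, median -0.06), and the median moved without 0 ppb replicate 5 (0.27) or 6 (0.38), or 3 ppb replicate 2 (0.23) or 4 (0.29). The 25 skeletal muscle markers rose by a median of 0.27, 16 above 0 (adjusted p = 0.0261, estimated-correlation p = 0.763). Of these, tnnt3a, a fast troponin T, was at 0.97 ± 0.56 (0.69) and myl1, a fast myosin light chain, at 0.85 ± 0.58 (-0.10). Skeletal muscle was at -0.20 without the 4 (0.718, reversed), with 0.0165 by block, 0.00220 to 0.962 in all and 4 of 6 slides higher. It lost the call without 0 ppb replicate 1 (0.0765, median 0.04), 3 (0.0566, median 0.01) or 5 (0.140, median -0.05, where camera kept its direction), or 3 ppb replicate 6 (0.398, median 0.00), and the median moved without 0 ppb replicate 4 (0.77), or 3 ppb replicate 1 (0.41), 2 (0.42), 3 (0.46) or 4 (0.01). Pancreas markers fell, 22 of 23 below 0, to a median of -1.62 (adjusted p = 0.00214, estimated-correlation p = 0.809). Here cpa5, a pancreatic carboxypeptidase, was at -2.95 ± 1.52 (-1.31) and ctrb.2 at -2.58 ± 1.51 (-1.13). Pancreas was at -0.68 without the 4 (0.0154), with 0.0102 by block, 1.80e-07 to 0.809 in all and 4 of 6 slides lower. The call was lost without 0 ppb replicate 1 (0.167, reversed, median 0.02). The 20 liver and vitellogenin markers fell to a median of -1.44, 19 below 0 (adjusted p = 0.0105, estimated-correlation p = 0.809). Of these, ttr, transthyretin, was at -1.71 ± 0.97 (-0.31) and serpina1l, a serine protease inhibitor, at -1.95 ± 1.42 (-0.64). Liver markers were at -0.48 without the 4 (0.483), with 0.0304 by block, 1.38e-06 to 0.946 in all and 3 of 6 slides lower. They lost or reversed the call without 0 ppb replicate 1 (0.0379, reversed, median 0.15) or 2 (0.108), or 3 ppb replicate 5 (0.0554). Thyroid hormone axis genes fell, 11 of 11 below 0, to a median of -0.64 (adjusted p = 0.0160, estimated-correlation p = 0.670). Here dio2 was at -3.14 ± 1.13 (-1.72) and ttr at -1.71 ± 0.97 (-0.31). The thyroid axis was at -0.17 without the 4 (0.129), with 0.0302 by block, 0.00634 to 0.695 in all and 6 of 6 slides lower. Its call was lost without 0 ppb replicate 1 (0.119, median -0.35), or 3 ppb replicate 6 (0.0642). Of the 2 probes of nr4a1, 1 had the sign given. Adjusted over the list alone, as over all genes, 0 members of any list were called at 3 ppb. Single omissions gave cpa5 at -1.1, ctrb.2 at -0.57, nr4a1 at 0.56 and ttr at -0.35 without 0 ppb replicate 1, tnnt3a at 0.48 without 0 ppb replicate 4, and myl1 at 0.41 without 3 ppb replicate 6.

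Of the 4 genes with the smallest p in each direction at 3 ppb, those above 0 ppb were iars1, the cytosolic isoleucyl-tRNA synthetase (1.35 ± 0.44, 1.06), zgc:154054 (1.21 ± 0.41, 0.80, n = 5 and 6), slc44a4, a choline transporter-like gene (1.42 ± 0.50, 0.94), and actn2b, an alpha-actinin (1.31 ± 0.48, 0.70). Besides zgc:158785, those below were slc17a6b (-1.21 ± 0.40, -0.53), nostrin, which binds nitric oxide synthase (-1.46 ± 0.49, -0.67), and fkbp5, a co-chaperone induced by glucocorticoids (-1.86 ± 0.64, -1.44). All 8 had an adjusted p of 0.911. The probes of iars1 had the same sign, from 0.75 to 3.90, and 4 of 5 probes of zgc:154054 did. Leaving 1 library out gave slc44a4 at 0.86 without 0 ppb replicate 1.

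In the reproductive panel at 3 ppb none was called. Steroid synthesis genes were at star 1.14 ± 1.24 (0.07, 0.33 to 1.94), cyp17a1 1.02 ± 1.22 (-0.47, 0.09 to 1.73), cyp11c1 0.64 ± 0.84 (-0.14, 0.10 to 1.12) and cyp19a1a -0.02 ± 0.38 (0.15, -0.14 to 0.16), receptors at ar -0.33 ± 0.32 (-0.01, -0.46 to -0.07), esr1 -0.58 ± 0.32 (-0.31, -0.79 to -0.38), esr2a -0.17 ± 0.50 (0.34, -0.44 to 0.26), esr2b -0.34 ± 0.54 (-0.15, -0.68 to -0.05), fshr 0.11 ± 0.84 (-0.81, -0.45 to 0.42) and lhcgr -0.67 ± 0.46 (-0.21, -0.86 to -0.25), and the somatic signals at amh 0.98 ± 1.31 (-0.38, -0.16 to 1.91), insl3 1.88 ± 1.25 (0.50, 0.64 to 2.58), igf3 -0.09 ± 0.45 (0.02, -0.44 to 0.23), gsdf 0.79 ± 1.24 (-0.55, -0.24 to 1.62) and dmrt1 1.03 ± 0.94 (-0.13, 0.32 to 1.63). insl3, a hormone of Leydig cells, was higher on 4 of 6 slides. Probes of ar, fshr and dmrt1 differed in sign. Far from its group was 1 library, with cyp17a1 at 1.65, lhcgr at -0.25, dmrt1 at 1.63, amh at 1.91 and gsdf at 1.62 without 3 ppb replicate 6.

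Called at another dose but not at 3 ppb were neuroendocrine genes at -0.40 (0.115, -0.02), the IGF list at -0.34 (0.135, -0.14), granulosa markers at 0.39 (0.167, -0.26) and xenobiotic metabolism at -0.41 (0.181, 0.02). Also among these were smooth muscle at 0.07 (0.185, -0.08), macrophage markers at -0.72 (0.227, -0.36), endothelium at -0.54 (0.390, -0.19) and adipocyte markers at -0.42 (0.598, 0.22). The rest were fibroblast genes at -0.29 (0.828, -0.13) and cholesterol synthesis at -0.19 (0.941, 0.09). None of these was called without the 4. Of 70489 genes and unnamed targets tested at 3 ppb, limma called 0 (smallest adjusted p = 0.911), with 1672 at an unadjusted p under 0.05, 162 of them higher and 1510 lower. A plain two-sample test also called 0, with 825 at that p, as did limma with the slide as a block, with 2884, and with the scan day as a block, with 2998. The median of all genes was -0.19. Without the 4, 0 were called and 688 lay under 0.05. The count of 1672 became 896, 2844, 4207, 3695 and 883 without 0 ppb replicates 1, 2, 3, 4 and 6 in turn, and 2965 without 3 ppb replicate 6. Camera called 11 of 35 lists at 3 ppb, and 0 with an estimated correlation or by fry.

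At 30 ppb, the highest dose, pancreas markers fell to a median log2 change of -2.73, and lists of macrophages, endothelium, fibroblasts and smooth muscle fell to medians of -1.26, -0.74, -1.21 and -0.93. Cell cycle, meiosis and spermatid lists rose, by 1.35, 1.70 and 1.18. Without the 4, these 8 medians were -0.88, -0.48, -0.20, -0.15, -0.27, 0.00, 0.03 and -0.21, and none was called with an estimated correlation (adjusted p = 0.670 to 0.809). Among single genes, ba1l, a beta-type globin, was at -3.04 ± 0.76 (SE, -2.32 without the 4, adjusted p = 0.675 by limma), and no single gene passed.

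Cell cycle genes rose, 30 of 31 above 0, by a median of 1.35 (adjusted p = 4.13e-11, estimated-correlation p = 0.670). Here mcm4, a subunit of the replicative helicase, was at 1.82 ± 0.74 (0.36) and mcm5, another subunit, at 1.97 ± 0.85 (0.37). The cell cycle was at 0.00 without the 4 (0.255, reversed), with 1.58e-10 by block, 8.29e-15 to 0.899 in all and 2 of 6 slides higher. It had another median without 0 ppb replicate 1 (0.69) or 6 (0.88). The 14 meiosis genes rose by a median of 1.70, 14 above 0 (adjusted p = 1.41e-06, estimated-correlation p = 0.690). Of these, psmc3ip was at 2.22 ± 0.99 (0.19) and rec8b, a subunit of meiotic cohesin, at 2.22 ± 1.11 (-0.01). Meiosis was at 0.03 without the 4 (0.688, reversed, unlike the median), with 2.84e-06 by block, 7.09e-09 to 0.962 in all and 3 of 6 slides higher. The median moved without 0 ppb replicate 1 (0.88). Spermatid and sperm flagellum genes rose, 23 of 24 above 0, by a median of 1.18 (adjusted p = 1.41e-06, estimated-correlation p = 0.763). Here zmynd10 was at 2.2 ± 1.11 (0.03, n = 4 and 5) and odf2b at 1.38 ± 0.71 (0.06). Spermatid genes were at -0.21 without the 4 (1.94e-05, reversed), with 4.96e-06 by block, 2.75e-09 to 0.763 in all and 3 of 6 slides higher. The median changed without 0 ppb replicate 1 (0.47) or 6 (0.74). The 18 spermatogonial and early germ cell markers rose by a median of 1.21, 14 above 0 (adjusted p = 0.000120, estimated-correlation p = 0.670). Of these, dnd1, a germ-cell RNA-binding protein, was at 3.12 ± 1.19 (0.95) and dazl at 2.67 ± 1.12 (0.18, n = 5 and 5). Spermatogonial markers were at 0.30 without the 4 (0.158), with 0.000152 by block, 4.46e-06 to 0.727 in all and 5 of 6 slides higher. They took another median without 0 ppb replicate 1 (0.72). DNA methylation and chromatin modifiers rose, 21 of 27 above 0, by a median of 0.59 (adjusted p = 0.000112, estimated-correlation p = 0.670). Here eed, a subunit of Polycomb repressive complexes, was at 0.58 ± 0.23 (0.44) and prmt1 at 0.93 ± 0.39 (0.32). Chromatin modifiers were at 0.18 without the 4 (0.558), with 0.000190 by block, 1.63e-07 to 0.902 in all and 5 of 6 slides higher. They had another median without 0 ppb replicate 1 (0.29). The 9 granulosa and theca markers, 7 also in other lists, rose by a median of 0.68, 8 above 0 (adjusted p = 0.0458, estimated-correlation p = 0.763). Of these, cyp19a1a was at 0.78 ± 0.38 (0.85) and amh, anti-Müllerian hormone, at 2.21 ± 1.31 (-0.08). Granulosa markers were at -0.13 without the 4 (0.278, reversed), with 0.0479 by block, 0.0133 to 0.763 in all and 3 of 6 slides higher. They lost the call without 0 ppb replicate 1 (0.333, median 0.34) or 6 (0.260), or 30 ppb replicate 1 (0.0527), 2 (0.0555), 4 (0.0626) or 5 (0.0791). Of the 2 probes of cyp19a1a, 1 had the sign given. Omission of 1 library gave cyp19a1a at 0.49 without 30 ppb replicate 1.

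Pancreas markers fell, 22 of 23 below 0, to a median of -2.73 (adjusted p = 2.17e-08, estimated-correlation p = 0.670). Here cpa5 was at -5.0 ± 1.52 (-2.74) and prss59.2, a trypsinogen, at -4.27 ± 1.51 (-2.92). Pancreas was at -0.88 without the 4 (8.38e-07), with 3.41e-07 by block, 2.68e-14 to 0.695 in all and 4 of 6 slides lower. The median moved without 0 ppb replicate 1 (-0.97). The 20 liver and vitellogenin markers fell to a median of -1.24, 20 below 0 (adjusted p = 0.00883, estimated-correlation p = 0.809). Of these, fabp10a, the liver fatty acid-binding protein, was at -2.56 ± 1.80 (-0.59) and ces3, a carboxylesterase, at -1.79 ± 1.30 (-0.34). Liver markers were at 0.14 without the 4 (0.906, where camera kept its direction), with 0.0208 by block, 7.27e-06 to 0.970 in all and 4 of 6 slides lower. The call was lost without 0 ppb replicate 1 (0.282, reversed, median 0.26) or 2 (0.0695), or 30 ppb replicate 6 (0.0521). Adipocyte markers fell, 10 of 12 below 0, to a median of -0.80 (adjusted p = 0.00599, estimated-correlation p = 0.670). Here fabp4a, a fatty acid-binding protein, was at -2.78 ± 0.94 (-1.97) and cidec, a lipid droplet protein, at -2.51 ± 0.92 (-1.67). Adipocyte markers were at -0.15 without the 4 (0.169), with 0.0165 by block, 0.00150 to 0.695 in all and 5 of 6 slides lower. The median changed without 0 ppb replicate 1 (-0.36). The 11 thyroid hormone axis genes fell to a median of -0.93, 8 below 0 (adjusted p = 0.0118, estimated-correlation p = 0.670). Of these, dio2 was at -3.22 ± 1.13 (-1.30) and dio3a at -0.93 ± 0.51 (-0.36). The thyroid axis was at -0.36 without the 4 (0.0409), with 0.0204 by block, 0.00538 to 0.695 in all and 5 of 6 slides lower. The call ended without 30 ppb replicate 1 (0.0967), and the median moved without 0 ppb replicate 1 (-0.56). IGF and insulin signalling genes fell, 16 of 21 below 0, to a median of -0.59 (adjusted p = 0.0222, estimated-correlation p = 0.779). Here igfbp5b, an IGF-binding protein, was at -2.79 ± 0.95 (-1.75) and igf2b, an IGF ligand, at -2.85 ± 1.02 (-1.23). The IGF list was at 0.14 without the 4 (0.918, where camera kept its direction), with 0.0300 by block, 0.00691 to 0.962 in all and 4 of 6 slides lower. Its call was lost without 0 ppb replicate 1 (0.245, median -0.03) or 6 (0.0530). Single omissions gave cpa5 at -3.15 and ces3 at -0.14 without 0 ppb replicate 1, fabp4a at -1.80 without 30 ppb replicate 1, and fabp10a at -1.58 without 30 ppb replicate 4.

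Macrophage and granulocyte markers fell, 19 of 20 below 0, to a median of -1.26 (adjusted p = 0.000327, estimated-correlation p = 0.763). Here npsn, a neutrophil protease, was at -1.63 ± 0.67 (-1.28) and lcp1, the leukocyte plastin, at -2.31 ± 1.1 (-1.39). Macrophage markers were at -0.48 without the 4 (0.000140), with 0.00137 by block, 2.56e-05 to 0.763 in all and 4 of 6 slides lower. They took another median without 0 ppb replicate 6 (-0.65). The 17 endothelial markers fell to a median of -0.74, 16 below 0 (adjusted p = 0.000428, estimated-correlation p = 0.763). Of these, aqp1a.1, a water channel of vessels and red cells, was at -2.76 ± 1.13 (-1.46) and etsrp, a factor of vessel development, at -0.68 ± 0.31 (-0.42). Endothelium was at -0.20 without the 4 (0.00727), with 0.000810 by block, 0.000104 to 0.763 in all and 5 of 6 slides lower. It had another median without 0 ppb replicate 1 (-0.47). Fibroblast and matrix genes fell, 15 of 16 below 0, to a median of -1.21 (adjusted p = 0.00221, estimated-correlation p = 0.809). Here ogna, osteoglycin, was at -1.41 ± 0.60 (-0.36) and fn1b, a fibronectin, at -2.89 ± 1.39 (-0.88). Fibroblast genes were at -0.15 without the 4 (0.0154), with 0.00233 by block, 6.34e-05 to 0.809 in all and 5 of 6 slides lower. They lost the call without 0 ppb replicate 6 (0.169, median -0.37). The 11 smooth muscle markers fell to a median of -0.93, 10 below 0 (adjusted p = 0.0262, estimated-correlation p = 0.809). Of these, desmb, a desmin, was at -2.17 ± 0.98 (-1.05) and myl9b, a regulatory myosin light chain, at -1.25 ± 0.82 (-0.31). Smooth muscle was at -0.27 without the 4 (0.00112), with 0.0286 by block, 0.000846 to 0.832 in all and 5 of 6 slides lower. The call was lost without 0 ppb replicate 3 (0.112), 5 (0.0526) or 6 (0.230, median -0.26), or 30 ppb replicate 1 (0.157). Leaving 1 library out gave aqp1a.1 at -1.72 without 0 ppb replicate 6, and desmb at -1.27 without 30 ppb replicate 1.

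Erythrocyte and circadian clock lists were not called at 30 ppb, but single members passed when adjusted over the list alone, against 0 adjusted over all genes. Brackets hold the change ± SE, the change without the 4 and the adjusted p. Of the erythrocyte markers 5 passed: hbba1, a beta globin (-3.24 ± 0.96, -2.46, 0.0365), alas2, the first enzyme of haem synthesis in red cells (-2.41 ± 0.76, -1.60, 0.0365), klf1, an erythroid transcription factor (-1.93 ± 0.65, -1.27, 0.0398), epb41b, a membrane skeleton gene (-1.27 ± 0.45, -0.83, 0.0437), and hbaa1, an alpha globin (-2.61 ± 0.97, -1.87, 0.0460). Each was lower on 6 of 6 slides, except epb41b on 5. Of these 5, 0 passed without the 4, 0 without 0 ppb replicate 1, 5 or 6, or 30 ppb replicate 1, 2, 3 or 4, and 3 without 3 ppb replicate 1, 2 or 4. Of the clock genes 3 passed: nr1d1, a repressor of the clock (-2.60 ± 0.68, -1.40, 0.0252), nfil3-6 (-2.47 ± 0.74, -1.1, 0.0426) and bhlhe40, another repressor of clock genes (-3.51 ± 1.11, -2.30, 0.0431). These 3 were lower on 6 of 6 slides. Of these 3, 1 passed without the 4, 0 without 0 ppb replicate 1 or 6, or 30 ppb replicate 1, and 1 without 0.3 ppb replicate 3 or 6, or 3 ppb replicate 1 or 2, or 30 ppb replicate 2, 3 or 4.

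Of the 4 genes with the smallest p in each direction at 30 ppb, those above 0 ppb were si:ch211-272h9.3 (1.51 ± 0.36, 1.08, n = 5 and 6), tigarb, a regulator of glycolysis (1.40 ± 0.35, 1.38), epyc, a small proteoglycan (1.35 ± 0.36, 1.22), and si:dkey-81n2.1 (1.59 ± 0.44, 0.94). Those below were ba1l, nr1d1, krt15, a keratin (-3.38 ± 0.93, -2.49), and lpin1a, a phosphatidate phosphatase (-2.39 ± 0.66, -1.22). All 8 had an adjusted p of 0.675.

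The reproductive panel held no called gene at 30 ppb. Values in steroid synthesis were star 1.87 ± 1.30 (0.00, 1.06 to 2.49, n = 5 and 6), cyp17a1 1.27 ± 1.22 (-0.84, 0.34 to 1.99), cyp11c1 0.79 ± 0.84 (-0.47, 0.26 to 1.18) and cyp19a1a 0.78 ± 0.38 (0.85, 0.49 to 0.96), those of receptors ar -0.45 ± 0.33 (-0.01, -0.58 to -0.19, n = 5 and 6), esr1 -0.21 ± 0.34 (-0.03, -0.42 to 0.00, n = 5 and 6), esr2a -0.65 ± 0.50 (0.13, -0.93 to -0.23), esr2b 0.28 ± 0.54 (0.18, -0.11 to 0.54), fshr 0.33 ± 0.84 (-0.88, -0.23 to 0.64) and lhcgr -0.58 ± 0.46 (-0.54, -0.72 to -0.36), and those of somatic signals amh 2.21 ± 1.31 (-0.08, 1.08 to 2.79), insl3 2.29 ± 1.25 (0.35, 1.05 to 3.00), igf3 0.46 ± 0.45 (0.43, 0.11 to 0.78), gsdf 1.82 ± 1.24 (-0.35, 0.79 to 2.37) and dmrt1 1.78 ± 0.94 (0.02, 1.07 to 2.19). star and insl3 were higher on 3 of 5 and 4 of 6 slides. Probes of ar, fshr, esr2b, cyp17a1, lhcgr and dmrt1 differed in sign. Far from its group was 1 library, with cyp19a1a at 0.49 and esr2b at -0.11 without 30 ppb replicate 1.

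Not called at 30 ppb, though called at another dose, were oocyte markers at 0.55 (0.107, -0.05), xenobiotic metabolism at -0.48 (0.151, 0.24), skeletal muscle at -0.41 (0.188, -0.50) and neuroendocrine genes at -0.21 (0.381, 0.28). Further such lists were immediate early genes at -0.05 (0.390, -0.25) and cholesterol synthesis at -0.01 (0.993, 0.07). Called lower only without the 4 were erythrocyte markers (adjusted p = 0.000581), skeletal muscle (0.000720), immediate early genes (0.00120), Sertoli cell markers (0.0147) and interferon response (0.0256), with adjusted p = 0.649 to 0.655 with an estimated correlation. Of 70480 genes and unnamed targets tested at 30 ppb, limma called 0 (smallest adjusted p = 0.675), with 4201 at an unadjusted p under 0.05, 2675 of them higher and 1526 lower. A plain two-sample test also called 0, with 2628 at that p, as did limma with the slide as a block, with 4992, and with the scan day as a block, with 5545. The median of all genes was -0.09. Without the 4, 0 were called and 3073 lay under 0.05. The count of 4201 became 1862, 6488, 7421, 7725 and 2733 without 0 ppb replicates 1, 2, 3, 4 and 6 in turn. Camera called 15 of 35 lists at 30 ppb, and 0 with an estimated correlation or by fry.

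Of the 35 lists, 14 were called at no dose, and for these the medians of the log2 change at 0.3, 3 and 30 ppb follow, with camera's adjusted p at the same doses in brackets and then the medians without the 4. Markers of Leydig cells, which make androgens, were at 0.53, 1.02 and 1.27 (0.455, 0.135 and 0.181), or -0.24, -0.14 and -0.02, and those of Sertoli cells, which nurse germ cells, at -0.10, -0.30 and -0.15 (0.620, 0.962 and 0.680), or -0.34, -0.11 and -0.12. Steroid hormone synthesis was at -0.02, -0.04 and 0.17 (0.575, 0.665 and 0.433), or -0.08, 0.02 and -0.02, sex steroid, gonadotropin and activin signalling at -0.19, -0.09 and 0.03 (0.0595, 0.598 and 0.613), or -0.28, -0.15 and 0.12, and estrogen-responsive genes at -0.20, -0.39 and -0.31 (0.433, 0.302 and 0.575), or 0.21, 0.02 and 0.09. Retinoic acid pathway genes were at -0.28, -0.26 and -0.41 (0.0765, 0.865 and 0.405), or -0.14, 0.00 and 0.11 and clock genes at -0.24, -0.22 and -0.27 (0.0624, 0.651 and 0.227), or -0.12, -0.05 and 0.11. Among stress and immune lists, oxidative stress was at -0.26, -0.22 and -0.42 (0.323, 0.779 and 0.192), or -0.19, -0.05 and -0.02, heat shock and unfolded protein response at -0.17, -0.15 and 0.10 (0.753, 0.665 and 0.598), or -0.12, -0.04 and 0.03, interferon and inflammation at 0.00, -0.31 and -0.66 (0.306, 0.985 and 0.167), or -0.10, -0.01 and -0.10, and lymphocyte markers at 0.10, -0.21 and -0.16 (0.588, 0.990 and 0.904), or -0.19, -0.23 and -0.01. Erythrocyte markers were at -0.34, 0.03 and -0.14 (0.207, 0.207 and 0.0753), or -0.19, -0.23 and -0.30, intestine and epithelium at 0.10, -0.15 and -0.19 (0.985, 0.468 and 0.133), or 0.20, 0.18 and 0.24, and peritoneum and duct at 0.01, -0.18 and -0.13 (0.802, 0.596 and 0.904), or 0.21, 0.22 and 0.24. Median, mean and test differed in sign in 12 of the 105 results, of which 0 were called: immediate early genes, intestine, macrophages and peritoneum at 0.3 ppb, heat shock, interferon, intestine, peritoneum, Sertoli cells, sex steroid signalling and steroid synthesis at 3 ppb, and lymphocytes at 30 ppb. Without the 4, they differed in 25, of which 8 were called over all libraries and 0 without the 4.

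Taking the doses together, genes with the smallest p for the mean of the 3 doses against 0 ppb were si:ch211-272h9.3 1.23 ± 0.28, si:dkey-83f18.3 1.28 ± 0.33, si:dkey-83f18.5 1.04 ± 0.28 and dio2 -3.44 ± 0.93 (log2 change ± SE). Along dose rank, they were tigarb 0.47 ± 0.11, mpp2b 0.40 ± 0.10, ba1l -0.92 ± 0.24 and epyc 0.42 ± 0.11 (log2 change per rank ± SE). For any difference among the 4 groups they included si:ch211-272h9.3, atp1a2a and slc17a6b. For the mean of the 3 doses, limma called 0 of 70479 (smallest adjusted p = 0.738), with 3185 at an unadjusted p under 0.05, 1044 higher. Limma's count was 1087 without the 4, and 1064, 6221, 7566, 7959 and 1616 without 0 ppb replicates 1, 2, 3, 4 and 6 in turn, 6394 without 0.3 ppb replicate 4, and 5080 without 3 ppb replicate 6. Along dose rank, limma called 0 of 70479 (smallest adjusted p = 0.646), with 4355 at an unadjusted p under 0.05, 2548 higher. Limma's count was 3213 without the 4, and 2076, 7962, 7720 and 2873 without 0 ppb replicates 1, 3, 4 and 6 in turn, and 7154 without 3 ppb replicate 6. In the F test of any difference, limma called 0 of 70479 (smallest adjusted p = 0.978), with 1239 at an unadjusted p under 0.05. Limma's count was 2504 without the 4, and 2089 and 2077 without 0 ppb replicates 3 and 4 in turn, and 1886 without 3 ppb replicate 6.

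Between doses, genes with the smallest p included si:dkey-169i5.4 -1.89 ± 0.60, commd5 -1.46 ± 0.48 and trpm1a -1.97 ± 0.67 at 3 against 0.3 ppb, mterf4 1.65 ± 0.39, atp1a2a 2.21 ± 0.54, mtmr1b 1.17 ± 0.29 and nrn1b 1.53 ± 0.42 at 30 against 0.3 ppb, and ino80c -1.5 ± 0.43, lto1 2.81 ± 0.84, atp1a2a 1.79 ± 0.54 and si:ch211-5k11.8 -3.07 ± 1.00 at 30 against 3 ppb. atp1a2a encodes a sodium pump subunit, and mterf4 a mitochondrial ribosome assembly factor. At 3 against 0.3 ppb, limma called 0 of 70489 (smallest adjusted p = 1.00), with 914 at an unadjusted p under 0.05, 171 higher. A plain two-sample test called 0, with 1501 under 0.05. Limma's count was 2660 without the 4, and 1535, 1444 and 554 without 0.3 ppb replicates 1, 2 and 6 in turn, and 556 and 1893 without 3 ppb replicates 1 and 6 in turn. At 30 against 0.3 ppb, limma called 0 of 70480 (smallest adjusted p = 0.951), with 2818 at an unadjusted p under 0.05, 1729 higher. A plain two-sample test called 1, with 4072 under 0.05. Limma's count was 5758 without the 4 (2 called), and 1596 without 0.3 ppb replicate 4. At 30 against 3 ppb, limma called 0 of 70479 (smallest adjusted p = 1.00), with 955 at an unadjusted p under 0.05, 768 higher. A plain two-sample test called 0, with 2120 under 0.05. Limma's count was 2508 without the 4, and 1473 without 0 ppb replicate 6.

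Genes above or below 0 ppb were compared between doses, which share the 6 controls. Limma called no gene, so the overlap of calls was 0. At an unadjusted p under 0.05 and a 1.5-fold change, 379, 355 and 364 genes were shared in direction between 0.3 and 3, 0.3 and 30, and 3 and 30 ppb, 41, 151 and 91 of them higher and 338, 204 and 273 lower. Independent lists of these sizes would share 33.54, 57.09 and 38.62, and simulated unchanged groups with shared controls 727, 722 and 720. The simulation decides nothing, as 0 ppb replicates 1 and 6 were low in germ cell transcripts. Log2 changes correlated across 70479 genes at 0.73, 0.59 and 0.72 (simulated 0.50, 0.50 and 0.50), with covariances of 0.256, 0.255 and 0.311 (simulated 0.198, 0.198 and 0.199); genes are not independent replicates. With the controls split 3 and 3, the correlations were -0.08, -0.07 and 0.00, the covariances -0.05, -0.05 and 0.00 and the shared genes 31.4, 42.5 and 37.6, as means over 20 splits.

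The authors' deposited table of each dose gives log2 values with no stated direction. At 30 ppb the largest sizes in the authors' deposited table belonged to digestive enzymes, keratins and a globin, PRSS2 (prss59.1) -5.27, CPA1 (cpa5) -5.11, KRT8 (krt4) -4.60, KRT17 (krt15) -3.88 and HBE1 (ba1l) -3.72. At 0.3 ppb the largest sizes in the authors' deposited table included DIO2 (dio2) -3.92, IARS (iars1) 3.71, ELOVL6 (elovl6) -3.55 and APOM (apom) -3.28. At 3 ppb the authors' deposited table led with IARS (iars1) 3.94, PPP1R3G (si:ch211-152c8.5) -3.35, DIO2 (dio2) -3.09, CPA1 (cpa5) -3.01 and ELOVL6 (elovl6) -2.95. By limma, at the brightest probe, elovl6 was at -1.72 ± 0.88 and -1.01 ± 0.88 at 0.3 and 3 ppb and apom at -3.20 ± 1.19 (n = 6 and 5) at 0.3 ppb, and without 0 ppb replicate 1, far from its group, at -0.63, 0.07 and -1.5. The authors' deposited tables hold 1088, 852 and 1321 probes at 0.3, 3 and 30 ppb, in 1098, 860 and 1334 entries, 483, 188 and 379 higher and 615, 672 and 955 lower. As these lists were chosen on the same samples, their direction here is not independent evidence: 1088, 852 and 1317 of 1088, 852 and 1319 probes went the way of the authors' deposited table, 669, 432 and 835 had an unadjusted p under 0.05 by limma and 0 passed adjustment. Probes listed at 2 doses in the authors' deposited tables carry the same p in 678 of 679 cases for 0.3 and 30 ppb, 570 of 570 for 0.3 and 3 ppb and 705 of 705 for 3 and 30 ppb, and 461 probes are listed at all 3 doses.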

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

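Tests weighed here were chosen after seeing the result, except groupings over all arrays and camera against 0 ppb, over all libraries or without 1.

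Within each dose group, the sample farthest from the others was marked where its gap to the next passed Dixon's critical value. This was so in 217 of 784 groups of values, where chance marks about 1 in 20. Most lay in 3 ppb replicate 6 (84), 0.3 ppb replicate 4 (65) and 0 ppb replicate 1 (28), with at most 12 in any other library. The rule can miss samples that lie far together, as for meiosis in 0 ppb replicates 1 and 6, so these counts rank no libraries. The 145 values of lists and genes named in the text follow.

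In 3 ppb replicate 6, list levels were chromatin modifiers -0.67, Leydig cell markers -2.57, Sertoli cell markers -0.94, the cell cycle -1.89, circadian clock 0.96, endothelium 2.70, pancreas 2.76, fibroblast genes 4.44 and granulosa markers -2.05. Then, list levels were heat shock 0.69, immediate early genes 2.38, the IGF list 1.53, meiosis -2.16, oxidative stress 0.64, retinoic acid pathway 1.00, smooth muscle 5.66, spermatogonial markers -1.71 and steroid hormone synthesis -1.23. Liver markers were at 2.49 and xenobiotic metabolism at 0.92. There log2 levels were ugt5a1 -4.14, mki67 1.30, tyms 0.43, ctrb.2 -0.83, igfbp2a 4.69, sycp1 4.35, psmc3ip 1.54, ghra 2.12, org 3.02, odf2b -1.91, dazl 3.62 and fgg 2.08. Next, log2 levels were nqo1 -1.63, cyp17a1 -0.74, lhcgr -5.34, dmrt1 -1.74, amh -3.51, gsdf 1.52, dnmt3bb.3 -1.48, plk1 2.75, nr4a1 1.62, myl1 0.50, ddx4 2.03 and serpina1l 2.74. As well, log2 levels were nr1d1 1.22, lpin1a -0.043, mcm4 2.25, mcm5 2.35, aqp1a.1 3.88, fn1b 9.3, igfbp5b 5.15, igf2b 3.59, rec8b 0.53, myl9b 7.77, dnd1 -1.97 and fabp10a 7.63. Then log2 levels were ces3 2.07, elovl6 1.67, epb41b 2.57, alas2 2.80, bhlhe40 3.69 and nfil3-6 1.09.

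In 0.3 ppb replicate 4, list levels were Leydig cell markers -3.40, the cell cycle -2.69, circadian clock 0.93, fibroblast genes 4.15, granulosa markers -2.36, immediate early genes 1.60, intestine 1.92, meiosis -3.52 and neuroendocrine genes -0.63. Then, list levels were sex steroid signalling -1.19, smooth muscle 3.96, spermatid genes -3.61, spermatogonial markers -2.50 and steroid hormone synthesis -1.78. Beyond these, log2 levels were mki67 1.41, cdk1 2.06, sycp1 2.22, psmc3ip 0.29, btg4 -4.64, org 1.37, zmynd10 -1.11, odf2b -1.98, rsph9 -0.35, dazl 2.29, esr2b -0.99 and dmrt1 -1.84. There log2 levels were amh -3.09, gsdf 1.22, cyp11c1 -0.51, actn2b -2.55, dnmt3bb.3 -1.69, plk1 1.36, ddx4 0.46, nr1d1 0.84, mcm5 2.70, ogna -2.66, fn1b 8.64 and rec8b -1.0. myl9b was at 6.55, dnd1 at -3.14 and elovl6 at 0.55.

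In 0 ppb replicate 1, list levels were pancreas 9.11, oxidative stress 1.54 and liver markers 8.66. Then, log2 levels were lpla 6.41, ctrb.2 9.75, nqo1 4.57, abcg2a 5.96, zgc:154054 -3.21, slc44a4 -1.99, cpa5 10.28, nr4a1 -3.78, ttr 6.40, etsrp 0.11, ces3 8.92 and elovl6 6.01. apom was at 8.96. In 30 ppb replicate 1, log2 levels were cyp19a1a -1.84, esr2b 3.94, cyp17a1 -0.50, epyc -1.38, fabp4a -4.31, igfbp5b -4.31, desmb -4.31 and nfil3-6 -3.55. In 30 ppb replicate 5, the list level was liver markers 3.36, with fgg 3.28, ces3 1.96 and klf1 -2.98. In 30 ppb replicate 6, list levels were chromatin modifiers 0.55, heat shock 0.59 and oocyte markers 0.49. In 0 ppb replicate 6, list levels were fibroblast genes 5.01 and smooth muscle 4.31, with aqp1a.1 5.47. In 3 ppb replicate 4, log2 levels were zgc:154054 1.02 and npsn 0.98. In 3 ppb replicate 3, the list level was oocyte markers 2.71, with abcg2a 1.64. In 0.3 ppb replicates 1, 3 and 5 in turn, log2 levels were abcg2a 2.46, npsn 0.96 and fkbp5 0.60. In 0 ppb replicate 4, the log2 level was tnnt3a -6.21.

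The counts of genes under an unadjusted p of 0.05 and of called lists do not exclude chance, by 100 groupings of the arrays into groups of the same sizes, the real one included. In the order 0.3, 3 and 30 ppb, mean, dose rank, 3 against 0.3, 30 against 0.3, 30 against 3 ppb and any dose, 55, 64, 24, 34, 20, 86, 35, 84 and 70 groupings gave at least the real 2173, 1672, 4201, 3185, 4355, 914, 2818, 955 and 1239 genes at that p, with medians of the others of 2360, 2287, 2084, 2034, 2008, 2308, 2055, 1741 and 1704 and highest others of 18710, 18967, 19307, 19021, 13950, 26963, 17344, 18556 and 15900. For lists called by camera with its preset correlation, 33, 46 and 13 groupings gave at least the real 13, 11 and 15 lists, with medians of 11, 10 and 10 and highest others of 21, 21 and 20. Limma called 0 genes in each real comparison, which all 100 groupings reach by construction, so these counts decide nothing, and the highest others were 2, 1, 2, 1, 2, 7926, 136, 1 and 1. With doses reassigned within each slide and the slide as a block, 27, 37 and 16 of 100 groupings gave at least the real 3507, 2884 and 4992 genes at 0.3, 3 and 30 ppb (medians 2448, 2454 and 2267, highest others 19727, 22177 and 21576) and 50, 55 and 24 the real 12, 11 and 15 lists (medians 11, 11 and 11, highest others 24, 21 and 21). Single groupings with several times the real count point to a structure of the samples.

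Germ cell transcripts were low and those of other tissues high in 0 ppb replicates 1 and 6, 0.3 ppb replicate 4 and 3 ppb replicate 6. Low signal alone would raise all other tissues alike, but the highest and lowest of their lists lay at least 4.51 log2 units apart in each (at most 3.44 in the other 20 libraries), and atrazine as the whole cause is argued against by the meiosis level of -5.14 in a 0 ppb library. RNA of other tissues stays open, as its test was void: at least 95.7% of members of the highest list (pancreas, fibroblasts, fibroblasts and smooth muscle) lay above their median, but that list was picked as the highest, and the 80% needed was passed in 8 of the other 20, with 100% in 30 ppb replicate 6. The most abundant genes of these lists stood at ela2 11.08 (median of the others 4.20) and prss1 11.03 in 0 ppb replicate 1, col1a2 8.36 (others 0.88) in 0 ppb replicate 6, 8.18 in 0.3 ppb replicate 4, and acta2 11.04 (others 3.73) in 3 ppb replicate 6. All 23, 16 and 11 pancreas, fibroblast and smooth muscle markers were above background on at least 10 of the other 20 arrays, and a change of the testis itself stays open, untested.

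Pancreas transcripts were lower at 30 ppb than at 0 ppb, at a median of -2.73. Without 0 ppb replicate 1, where they stood at 9.11, the median was -0.97 (adjusted p = 0.000846 by camera), where adjusted p over all libraries was 2.17e-08 and ran from 2.68e-14 to 0.695 over the alternatives, so pancreas RNA in that library could be part of the cause but not shown to be the whole. Against 0.3 and 3 ppb the medians at 30 ppb were -1.25 and -0.82 (camera p = 0.000274 and 1.70e-07, or 0.330 and 0.167 with an estimated correlation). A dose effect needed both below -1 and was excluded by 1 above -0.5, so only the first met its need and the second lay between. Pancreas RNA in that library as the whole cause needed a median of -0.5 to 0.5 without it and was excluded below -1, and -0.97 lay between. The 2 cannot be told apart, because neither was met in full or excluded.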

How the results depend on the processing

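Fits without sets of libraries, with marked spots kept or with named genes alone were chosen after the results were seen. With limma 0 genes were called in each comparison, and in 42 of 46 settings every count stayed at 0. Array weights called 1 at 30 against 0.3 ppb and 1 in the F test, a plain two-sample test 1 at 30 against 0.3 ppb, and the fit without the 4 libraries low in germ cell transcripts 2 there, all unnamed targets, and the cause was not tested. With an unadjusted p under 0.05 and a 1.5-fold change, by construction a looser threshold, the counts were 2159, 1670 and 4152 at 0.3, 3 and 30 ppb, 3079 for the mean, 653 for dose rank, 910, 2733 and 945 for 3 against 0.3, 30 against 0.3 and 30 against 3 ppb, and 1221 in the F test, and 876 genes were shared between doses. Counts that stay at 0 show no stability: with 1 library left out, 37 of 216 counts under an unadjusted p of 0.05 moved by over 1.5 times. Of 9856 values of single named genes 209 moved by 1 SD or more, 365 changed sign and 0 were called.

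The 39 calls of gene lists over the 3 doses became 0 with an estimated correlation and 0 by fry, 42 with quantile scaling, 43 with normexp, 40 without a filter, 28 without the 4 libraries (15 of them among the 39, 12 in the same direction, and 0 with an estimated correlation as well), 31 without the 3 arrays with poor spots and 24 without both sets, and lay between 30 and 43 with 1 library left out. Of the 39 called lists 1069 results kept direction and side of the threshold, 217 lost the call and 40 reversed. Without the 4 libraries, the lists reversed by camera (at 30 ppb the median of meiosis stayed above 0) had adjusted p of cell cycle 0.00409, 0.702 and 0.255 at 0.3, 3 and 30 ppb, granulosa 0.278 at 30 ppb, immediate early 0.0147 at 3 ppb, meiosis 0.597 and 0.688 at 0.3 and 30 ppb, skeletal muscle 0.718 at 3 ppb, spermatid 0.668 and 1.94e-05 at 3 and 30 ppb and spermatogonial 0.583 at 0.3 ppb, or, in that order and with an estimated correlation as well, 0.727, 0.962, 0.899, 0.655, 0.649, 0.960, 0.962, 0.962, 0.962, 0.649 and 0.902. Without both sets they had cell cycle 0.00427, 0.654 and 0.0363 at 0.3, 3 and 30 ppb, granulosa 0.518 at 30 ppb, immediate early 0.0330 at 3 ppb, IGF 0.940 at 30 ppb, meiosis 0.605 and 0.419 at 0.3 and 30 ppb, skeletal muscle 0.753 at 3 ppb, spermatid 0.817 and 2.80e-07 at 3 and 30 ppb, spermatogonial 0.556 at 0.3 ppb and liver 0.296 at 30 ppb. With 1 library left out, adjusted p ran over pancreas 1.80e-07 to 0.333 at 0.3 ppb, pancreas 1.80e-07 to 0.167 at 3 ppb, immediate early 7.74e-05 to 0.842 at 3 ppb, liver 1.38e-06 to 0.108 at 3 ppb and liver 7.27e-06 to 0.282 at 30 ppb, each reversed without 0 ppb replicate 1 or, for the immediate early genes, without 3 ppb replicate 6, and 78 of 468 medians moved by over 1.5 times. The cause was not tested, beyond the fewer libraries in these fits.

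Probes of the authors' deposited lists under an unadjusted p of 0.05 numbered 669, 432 and 835 at 0.3, 3 and 30 ppb, 331, 172 and 528 without the 4 libraries, 482 at 30 ppb without the 3 arrays, and 394, 201 and 455 without both, and the cause was not tested.

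Replicate numbers, which are also slides, did not meet the criterion for pairing, every pair over 0.1: of 36 pairs of same-numbered libraries 21 did so in their deviations from the group means (1, 5, 6, 3, 5 and 1 of 6 for numbers 1 to 6, range -0.48 to 0.52), and 11 of 24 libraries correlated best with their own number, against 4 expected by chance, a hint from the data that some slides share deviations. With the replicate block limma called 0 genes, and 38 list calls were made, without that of cholesterol synthesis at 0.3 ppb. It changed no other call. Signal over background limits what could be seen: 20257 genes and targets were well above background on all 24 arrays, against 70490 tested at 0.3 ppb.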
